A study of Mus musculus with 5 samples.

How the data were processed

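Germinal centre B cells were purified by flow cytometry from splenic mononuclear cells, per the labels' protocols. RNA was extracted with a NucleoSpin RNA XS kit and a small amount of total RNA was amplified with the NuGEN Ovation system before biotin labelling, per the labels' protocols. The authors deposited 1 table of MAS5 signal intensities on a linear scale, with 45101 probe sets and 5 arrays, and MAS5 is named in the submitters' processing notes without a version. In the deposited table the 2% trimmed mean of every array was 500, the form that MAS5 scaling gives. MAS5 scores each array by itself, subtracts mismatch probes and keeps no probe-level values, so low signals vary widely on a log scale. Detection calls were not used here. The settings of the scanner software are not given in the sources used here.

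Samples were grouped by the titles in the labels, as 3 WT and 2 REL arrays, and every column of the table was assigned to a sample. Probe sets were named from the platform annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none listed, and the table includes 64 control probe sets. Of those with 1 symbol, 34754 matched a RefSeq gene through the Entrez identifier and 0 symbols needed an update. The 1-symbol probe sets covered 18194 genes. Probe sets with several genes or none were left out of the gene comparison.

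Signals were transformed as log2(signal + 16) with no further normalization between arrays, so fold changes of dim genes are understated. Probe sets in the lowest 40% by mean over the 5 arrays (below a signal of about 23.1) were left out, and for each gene the probe set with the highest mean was kept, which left 22200 probe sets and 12082 genes. Where probe sets of a named gene pointed in opposite directions, this is stated beside the gene for those named by rank. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, group as the single term), with 3 residual and 6.84 prior degrees of freedom and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, two-sided. The number of arrays limits the precision, and the median SD between arrays of a group was 0.35 log2 units in WT and 0.36 in REL.

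The 29 gene lists were written before the data were examined, from general knowledge of B cells, NF-kB, metabolism and the other cell types a spleen sort could hold. Of their 810 memberships 715 are on the array, and members that did not pass the filter or carry no single name are not analysed here. Lists with at least 5 measured members were tested with camera in limma (preset inter-gene correlation 0.01, adjusted over the 29 lists). Camera with an estimated correlation and fry were run beside it. With the preset correlation 9 lists were called, with an estimated correlation 0, and by fry 1, the macrophage list.

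The genes named were fixed by rule before the data were examined. They are Rel with the NF-kB subunits and inhibitors, the genes called in each direction if at least 5 were, otherwise the 8 per direction with the smallest p whose arrays do not overlap (predicted genes left out, and stated as not past the threshold), and up to 4 members per list by smallest p in the list's direction. Of lists not called 2 members were named. Members that passed adjusted over the list alone, S100a8, S100a9 and Adgre1, members of lists not called that lay against the list's direction at an unadjusted p under 0.05 (Rgs13, Polh, Sdc1, Cr2, Gins3, Cenpa and Klf4), and the example genes of the closing section outside these rules, were named in addition after their values were seen.

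The fitting code was tested on simulated data with 12082 genes, 200 of them changed, over 20 runs of 3 against 2 arrays. It recovered 12% of 2-fold and 54.4% of 4-fold changes with 3.35 false calls per run, and 100% of lists of 40 genes shifted by 0.4 log2 units, while 0.6% of unshifted lists were called. The simulation assumed independent genes, while camera estimated correlations of 0.03 to 0.67 within the lists called lower. Those lists also lay nearer to the median of all genes than the simulated shift, at −0.06 to −0.24 relative to it. The simulated rates for lists therefore do not describe those calls.

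Alternatives fixed before the data were examined were a pseudocount of 1 or 64, no filter or a 60% filter, quantile normalization, median centring, the mean of a gene's probe sets, no mean-variance trend, the replicate number as a block, all probe sets, each array left out in turn, and the other list tests. Added after seeing the data were 10000 random lists matched on mean level, and leaving out each REL array, or adding a pseudocount of 1, while keeping the probe sets of the full comparison. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.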

Results

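The series measured gene expression in germinal centre B cells, the B cells that proliferate and mutate their antibody genes in lymphoid follicles after immunization. Cells were sorted by flow cytometry from the spleens of 12-week-old C57BL/6 littermates at day 7 after immunization with sheep red blood cells. The 3 WT arrays came from mice carrying the Cg1-Cre transgene alone. The 2 REL arrays came from eGFP-positive germinal centre B cells of mice that carried Cg1-Cre and loxP-flanked alleles of Rel, the gene for the NF-kB subunit c-Rel. Each sample was hybridized to 1 single-colour Affymetrix array. The labels do not say that each array came from a separate animal, so p-values measure the spread between these samples, which may be technical. Every array had a 2% trimmed mean signal of 500, and median signals were 40.7, 41.1 and 54.6 in WT replicates 1 to 3 and 48.1 and 30.1 in REL replicates 1 and 2. Across probe sets, which are not independent replicates, the log2 signals of the WT pairs had Pearson correlations of 0.92 to 0.937, those of a WT and a REL array 0.889 to 0.908, and those of the REL pair 0.882. The first principal component (33.6% of the variance) set REL replicate 2 apart from the other arrays, and the second (28.9%) set REL replicate 1 apart. The 3′ over 5′ signal ratio of Actb, a measure of RNA integrity, was 1.577, 1.732 and 2.448 in WT and 1.644 and 1.735 in REL. That of Gapdh was 1.43, 1.512 and 1.709 in WT and 1.417 and 1.571 in REL.

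The single comparison of the design asked how germinal centre B cells with floxed Rel alleles and Cg1-Cre differed from those with Cg1-Cre alone. Rel itself, measured by 1 probe set, had signals of 492, 134 and 206 in WT and 18.6 and 85.2 in REL. Both REL arrays lay below every WT array, and the difference was −2.12 on the log2 scale (SE 0.73), with a limma adjusted p of 0.46 over all genes. The labels do not say which exons the deletion removes, so a probe set outside the deleted part would not check the genotype. Of the other measured NF-kB subunits and inhibitors, Rela, the gene for the p65 subunit, was at −0.47 (SE 0.33), Relb at 0.14 (SE 0.45) and Nfkb2 at −0.39 (SE 0.51). The inhibitor genes Nfkbia, Nfkbib, Nfkbie, Nfkbiz and Bcl3 were at 0.06, 0.14, −0.45, 0.32 and −0.32, and the kinase subunits Ikbkb and Ikbkg at −0.07 and −0.14. The direction of Ikbkb and Ikbkg turned under median centring of the arrays (0.10 and 0.03). None of these 11 genes passed the threshold, over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.503 for the list.

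Vcam1, an adhesion molecule of macrophages and stromal cells, was the single gene called among 12082 tested. Its signal was 0.833 to 2.46 on the 3 WT arrays and 671 and 390 on the REL arrays, a log2 difference of 4.89 (SE 0.52, limma adjusted p = 0.0388) on the log2(signal + 16) scale. The WT signals lay below the level of dim probe sets (23.1), so the size of the change depends on the added 16, and the call was lost with 64 added in its place (3.13, adjusted p = 0.0521), with the mean of its 3 probe sets (2.03, adjusted p = 0.439), and, with the difference still at 4.89, with no filter (0.129) and without the mean-variance trend (0.103). With 1 added another Vcam1 probe set became the brightest (1.61, adjusted p = 0.732), and the probe set used here gave 7.58 (adjusted p = 0.0504), an alternative added after seeing the data. The call was also lost when any WT array was left out (adjusted p = 0.3, 0.478 and 0.328 without WT replicates 1, 2 and 3), with differences of 4.92, 4.86 and 4.91 and 2 residual degrees of freedom in place of 3. Without REL replicate 1 or 2 another Vcam1 probe set became the brightest and gave 0.20 and 2.03. The probe set used here, chosen with the left-out array included, gave 4.51 and 5.27, alternatives also added after seeing the data. No gene was called lower by limma, and at an unadjusted p under 0.05 there were 392 genes higher and 603 lower in REL, together 8.24% of the genes. Genes whose REL arrays all lay above or all below every WT array made up 9.53% and 14.3% of those tested, where chance gives 10% in each direction.

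The genes with the smallest p in each direction, apart from Vcam1, did not pass the threshold. Among those higher in REL were C1qb, which encodes a complement C1q chain made by macrophages (4.32, SE 0.60), Csf1r, the receptor for macrophage colony-stimulating factor (3.96, SE 0.57), Slc40a1, the iron exporter ferroportin (3.64, SE 0.55), and Mrc1, the macrophage mannose receptor (3.04, SE 0.52). Without REL replicate 1 or 2 another Csf1r probe set became the brightest (0.16 and 0.88), and the probe set used here, chosen with the left-out array included, gave 3.91 and 4.01. Smc2os (4.17), Fam135a (3.67) and the succinate dehydrogenase assembly factor Sdhaf4 (1.61) completed this group, and the adjusted p of these 7 genes ran from 0.126 to 0.248 in limma. Among those lower, Mrpl33, which encodes a mitochondrial ribosomal protein, was at −1.51 (SE 0.18, limma adjusted p = 0.0518), with signals of 6139 to 7616 in WT and 2474 and 2221 in REL. Plaat3 was at −2.01, Piwil2 at −3.57, C1qtnf12 at −3.36, the fatty acid desaturase gene Fads2 at −2.22 and the mitochondrial nuclease gene Endog at −1.75. Nr4a3, an orphan nuclear receptor gene, was at −3.30 and the interferon-induced Rsad2 at −2.96, and for each of these 1 of 2 probe sets pointed the other way (without WT replicate 1 that of Rsad2 was the brighter one, at 0.96). The adjusted p of these 7 genes ran from 0.18 to 0.248. The plot of signals per array shows all 16 genes and Rel.

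**Figure D1:**
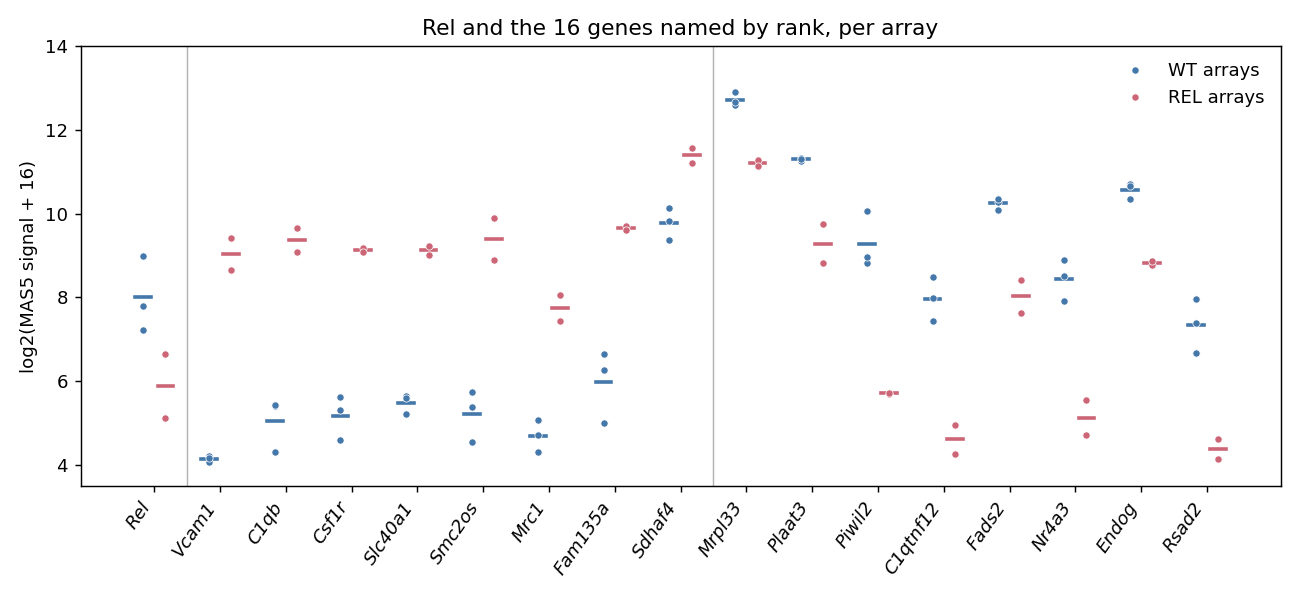
Signals of Rel and of the 16 genes named by rank, as log2(MAS5 signal + 16) on the vertical axis. Each point is 1 array (blue, WT; red, REL), bars are group means, and Vcam1 is the single gene past the threshold, with REL signals of 671 and 390.

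Markers of macrophages, monocytes and neutrophils rose in REL as a list. Of 15 measured members 11 were higher, with a median log2 difference of 1.51, and camera with a preset correlation gave an adjusted p of 1.65e-08. The adjusted p was 0.25 with an estimated correlation and 0.0398 by fry, which tests whether the members move one way on balance. With no filter on dim probe sets the median was 0.65 (adjusted p = 5.9e-09). The filter takes the mean over all 5 arrays, so that members dim in WT, such as Vcam1, passed it through their REL signals. By limma, 9 members passed when adjusted over the list alone and 1, Vcam1, over all genes. The 9 were Vcam1, C1qb, Csf1r, Slc40a1, the lysozyme genes Lyz1 (3.31) and Lyz2 (3.08), the phagocytic receptor gene Mertk (1.58), Mpeg1 (1.12) and the haem oxygenase gene Hmox1 (1.51), and in each both REL arrays lay above every WT array. The neutrophil genes S100a8 and S100a9 were both at −1.65 (S100a9 at 0.23 without REL replicate 2) and the macrophage gene Adgre1 was at −0.83, none past the threshold. Without REL replicate 1 the list's median was 0.20 (adjusted p = 0.145), because the filter on dim probe sets and the choice of the brightest probe set were remade on 4 arrays. With the probe sets of the full comparison it was 1.57, but these were chosen with REL replicate 1 included, so that value does not fully leave the array out. Without REL replicate 2 the list's median was 0.88, and 1.28 with the probe sets of the full comparison, to which the same limit applies.

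The list of follicular dendritic, stromal and endothelial cell markers rose by a median of 0.29 over 11 members (camera adjusted p = 0.0399), and with no filter on dim probe sets it was at 0.18 and not called (adjusted p = 0.0783). Its adjusted p was 0.714 with an estimated correlation, and without REL replicate 1 its median was −0.11 (adjusted p = 0.951). It shares Vcam1 with the macrophage list. Adjusted over the list alone, 2 members passed in limma, Vcam1 higher and the complement receptor gene Cr2 lower (−0.80, SE 0.24), against 1 over all genes. Pecam1 was at 1.25, Pdgfrb at 1.28 and Fcgr2b at 0.24. The natural killer and dendritic cell markers had a median of 0.63 over 7 members, with Flt3 at 0.98 and Prf1 at 1.15, and were not called (adjusted p = 0.0543). T cell markers (8 members, 0.19; Cd247 1.72, Cd2 0.17) and erythroid and platelet markers (7 members, −0.12; Hbb-b2 −1.87, Slc4a1 −1.24) were not called either.

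Lists of energy metabolism genes were called lower in REL by camera with the preset correlation. The median difference over all genes was −0.07, with 6866 genes below 0 and 5216 above, and the list test compares each list with the other genes. Oxidative phosphorylation, the electron transport and ATP synthase genes, fell with a median of −0.22 over 61 members, 51 of them lower (camera adjusted p = 2.11e-05, and adjusted p = 0.72 with an estimated correlation). Ndufa5 was at −0.87 (SE 0.19), Cyc1 at −0.87, Ndufv1 at −0.62 and Ndufb6 at −0.91. The TCA cycle list fell with a median of −0.25 over 21 members, 17 lower (adjusted p = 0.0156, and adjusted p = 0.705 with an estimated correlation), and it held Sdha at −0.59, Idh3g at −0.53, Idh3b at −0.50 and Fh1 at −0.48. Glycolysis fell with a median of −0.28 over 18 members, 15 lower (adjusted p = 0.0156, and adjusted p = 0.714 with an estimated correlation). Its members included Ldha, which encodes lactate dehydrogenase A (−0.52, SE 0.16), Pfkm (−1.72, SE 0.55), Pkm (−0.54, SE 0.17) and Aldoa (−0.28, SE 0.16). No member of these 3 lists passed in limma, over all genes or adjusted over the list alone.

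Lists of protein synthesis and turnover were called lower as well, also with the preset correlation. The proteasome list fell with a median of −0.20 over 31 members, 27 lower (camera adjusted p = 9.52e-04, and adjusted p = 0.714 with an estimated correlation), with Psmb7 at −0.57, Psmb5 at −0.55, Psmd1 at −0.56 and Psmd12 at −0.46. MYC target genes fell with a median of −0.19 over 36 members, 31 lower (adjusted p = 0.00304, and adjusted p = 0.705 with an estimated correlation). They included the DNA repair endonuclease gene Apex1 at −0.61 and Cad, the first enzyme of pyrimidine synthesis, at −1.40, and they share Ldha and Pkm with glycolysis. The aminoacyl-tRNA synthetases fell with a median of −0.31 over 19 members, 14 lower (adjusted p = 0.0156, and adjusted p = 0.714 with an estimated correlation), with Farsb at −0.75, Gars at −0.60, Aars at −0.79 and Hars at −0.40. Cytosolic ribosomal proteins fell with a median of −0.13 over 42 members, 38 lower (adjusted p = 0.0156, and adjusted p = 0.767 with an estimated correlation), among them Rps6 at −0.39, Rpl14 at −0.56, Rps26 at −0.26 and Rpl38 at −0.18. With quantile normalization the ribosomal protein median was −0.01 (adjusted p = 0.854), while the other lists called lower stayed called (camera adjusted p 0.00011 to 0.00886). The ribosomal protein median lay at percentile 11.9 of random lists matched on mean level, a comparison added after seeing the data. No member of these 4 lists passed over all genes or adjusted over the list alone. For Rps6 and Sdha the mean of all probe sets of the gene pointed the other way (0.56 and 0.16).

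None of the 7 lower lists was called without REL replicate 1 (adjusted p 0.463 to 0.602). The median of all genes was then −0.10, and relative to it glycolysis was at −0.13, the aminoacyl-tRNA synthetases at −0.16, the TCA cycle at −0.05, MYC targets at −0.02, oxidative phosphorylation and the proteasome at 0.01 and ribosomal proteins at 0.11, against −0.21, −0.24, −0.18, −0.12, −0.15, −0.13 and −0.06 with all arrays. Without REL replicate 2 the same lists were at −0.28, −0.22, −0.22, −0.21, −0.29, −0.31 and −0.23, each called (adjusted p 3.29e-09 to 0.00989). Glycolysis was not called without WT replicate 2 or 3 (adjusted p = 0.0588 and 0.0566), ribosomal proteins without either (0.441, with the list at 0.02 relative to all genes, and 0.0677) and the aminoacyl-tRNA synthetases without WT replicate 3 (0.0566). Median centring of the arrays moved the median of all genes from −0.07 to 0.10 and also called 0 of the lists, with each list's distance from that median as with all arrays uncentred. The fit without a mean-variance trend called 0 of them with the same medians, and its prior degrees of freedom were 2.6 in place of 6.8. Array by array, the median deviation of the oxidative phosphorylation genes from the WT mean was −0.13, 0.10 and 0.05 in WT and −0.32 and −0.08 in REL, so that REL replicate 2 lay within the WT range. The same held for the proteasome and ribosomal protein lists. For glycolysis (−0.31 and −0.22 in REL, lowest WT array −0.17), the TCA cycle (−0.25 and −0.14, lowest −0.09), MYC targets (−0.25 and −0.11, lowest −0.09) and the aminoacyl-tRNA synthetases (−0.25 and −0.26, lowest −0.07) both REL arrays lay below every WT array. The middle 18S ribosomal RNA probe set had signals of 9822, 8696 and 9154 in WT and 11953 and 13417 in REL, and the 5′ one 858, 536 and 293 in WT and 1671 and 1984 in REL. On the same arrays the macrophage list stood at 0.08, 0.18 and −0.21 in WT and at 1.28 and 1.57 in REL.

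**Figure D2:**
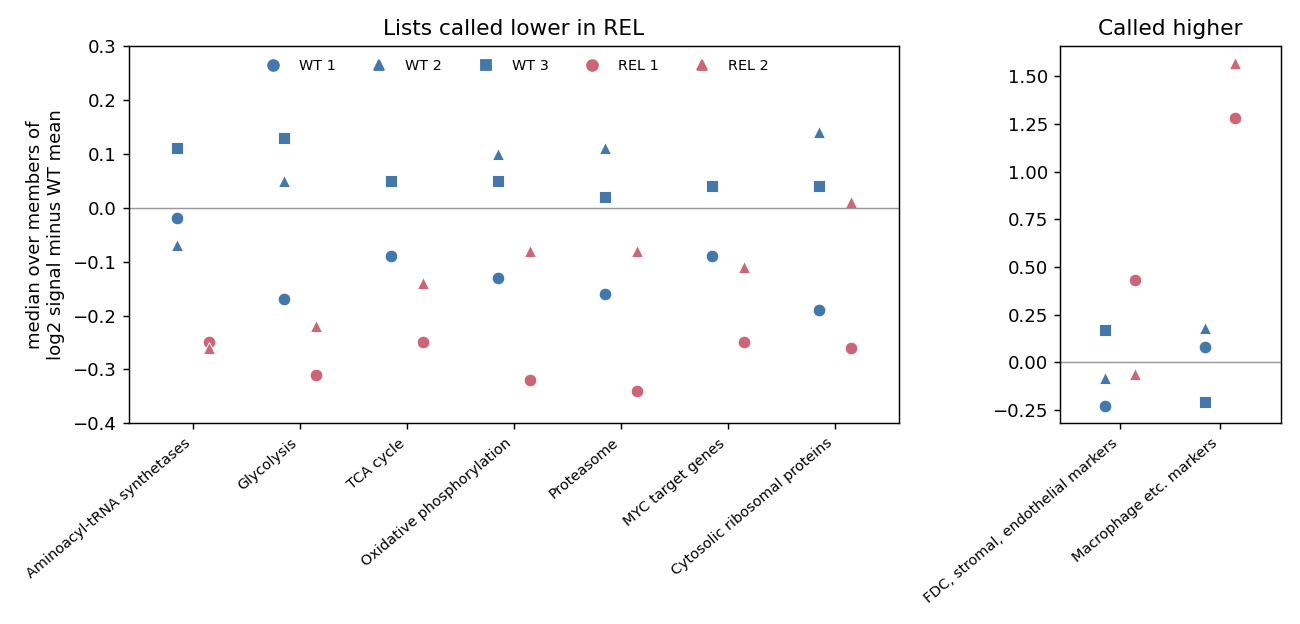
Median over list members of log2 signal minus the WT mean, for each array (vertical axis, log2 units; the panels have different scales), in the 7 lists called lower and the 2 called higher. Points are arrays (blue, WT; red, REL; shapes give the replicate), and in oxidative phosphorylation REL replicate 2 (−0.08) lies above WT replicate 1 (−0.13).

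The germinal centre programme itself was not called in either direction. NF-kB target genes in B cells had a median of 0.03 over 29 members (camera adjusted p = 0.503), with Cd44 at 0.70 (SE 0.24) and the apoptosis inhibitor gene Cflar at 0.61. Germinal centre B cell markers had a median of −0.03 over 21 members (adjusted p = 0.775), with the transcription factor gene Bach2 at 0.79 (SE 0.23), the DNA glycosylase gene Neil1 at 0.26 and Rgs13 lower at −0.54 (SE 0.19). Light zone genes stood at 0.05 over 22 members (adjusted p = 0.503), with the chemokine receptor gene Ccr6 at 0.87 and Egr2 at 0.85, and dark zone genes at −0.05 over 18 (adjusted p = 0.934), with Gadd45b at 0.32, Tcf3 at 0.51 and the DNA polymerase eta gene Polh lower at −0.44 (SE 0.15; 2 of its 4 probe sets pointed the other way). Plasma cell genes were at −0.03 over 16 members (adjusted p = 0.503), with Xbp1 at 0.49 and Edem1 at 0.48, and the syndecan gene Sdc1 at −1.96 (SE 0.66, signals 125 to 455 in WT and 42.6 and 42.4 in REL). Without WT replicate 1 another Sdc1 probe set became the brightest, at 1.26. Naive and follicular B cell markers were at 0.16 over 16 members (adjusted p = 0.492), with Bank1 at 0.28 and Klf2 at 0.53 and Cr2, also in this list, at −0.80, and MHC class II presentation at −0.05 over 10 (adjusted p = 0.934), with Ciita at 0.33 and H2-Aa at 0.10.

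Cell cycle and biosynthesis lists outside the called ones had medians below 0. Ribosome biogenesis was at −0.18 over 38 members (camera adjusted p = 0.0543), with Grwd1 at −1.20 and Nop58 at −0.75. DNA replication and G1/S genes were at −0.17 over 35 (adjusted p = 0.22), with Rpa2 at −0.77, Prim1 at −0.54 and Gins3 higher at 0.69. In G2/M and mitosis (−0.16 over 31, adjusted p = 0.18), the spindle checkpoint kinase gene Ttk (−1.45, SE 0.30) passed in limma when adjusted over the list alone and not over all genes, Cdkn3 was at −0.50 and Cenpa was higher at 0.46. Nucleotide and one-carbon synthesis was at −0.08 over 28 members (adjusted p = 0.36), with Phgdh at −0.73, and sterol and fatty acid synthesis at −0.21 over 23 (adjusted p = 0.503), with Cyp51 at −0.66 and Idi1 at −0.52. The unfolded protein response was at −0.02 over 22 members (adjusted p = 0.481), with Dnajb9 at 0.65 and Dnajc3 at 0.46. Apoptosis regulators had a mean of −0.02 over 21 members (adjusted p = 0.943), with Apaf1 at 0.45. Immediate-early and heat-shock genes had a median of 0.02 over 22 members (adjusted p = 0.386), with Egr3 at 0.51 and Klf4 lower at −1.23 (SE 0.52; −0.02 without WT replicate 1, from another probe set). Interferon-stimulated genes had a median of 0.11 and a mean of −0.18 over 20 members (adjusted p = 0.934), with Gbp3 at −1.35, and Rsad2 passed in limma adjusted over the list alone and not over all genes. The camera direction of the interferon list was down, against its median. For the germinal centre, dark zone, plasma cell, unfolded protein response, apoptosis and MHC class II lists it was up although the medians were at or below 0, since the test compares each list with the other genes.

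**Figure D3:**
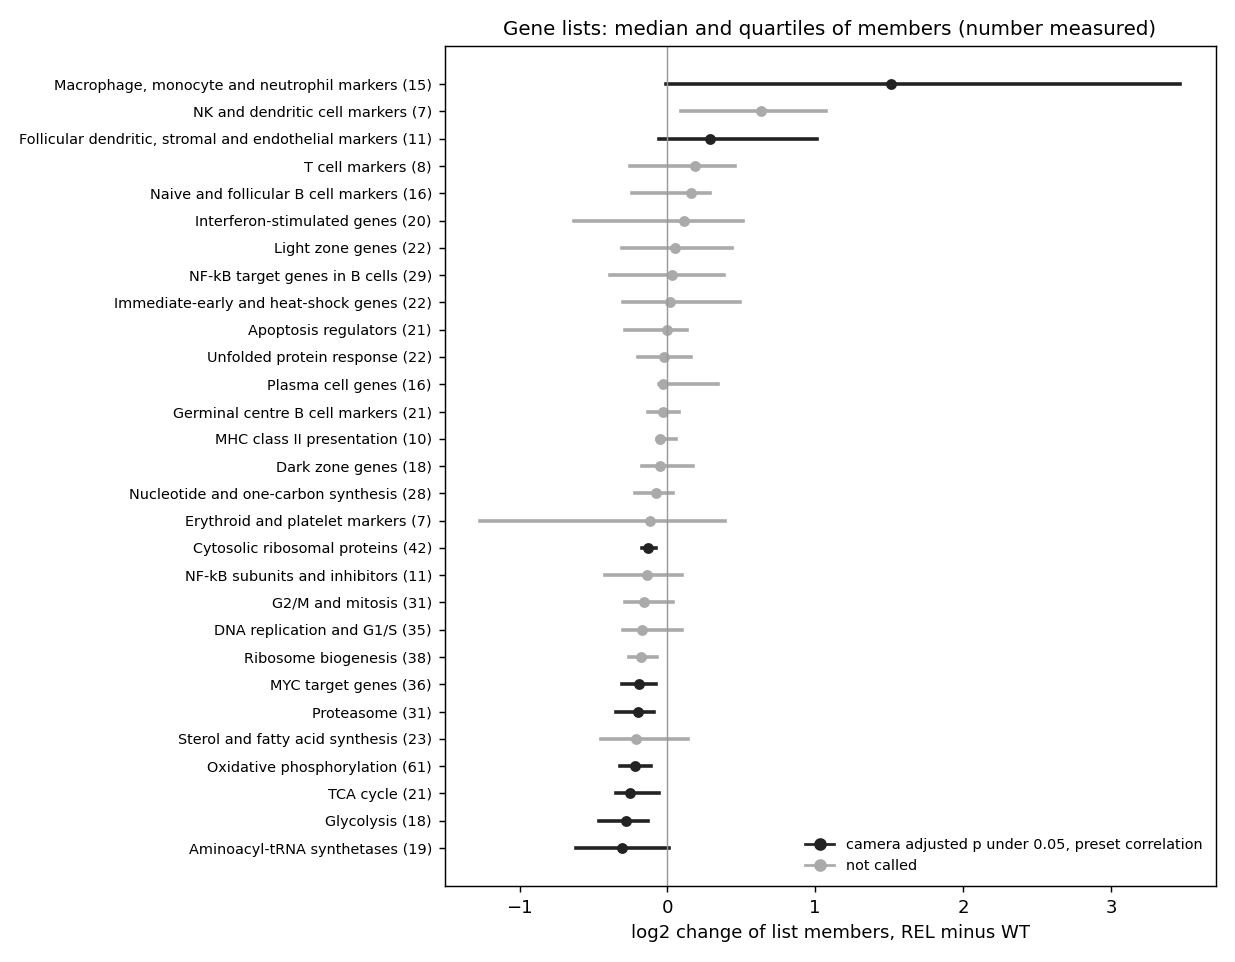
Median (point) and quartiles (line) of the log2 difference, REL minus WT, over the measured members of each of the 29 lists (horizontal axis, log2 units; number measured in parentheses). Black marks the 9 lists called by camera with a preset correlation, of which the macrophage list has the highest median (1.51) and the aminoacyl-tRNA synthetases the lowest (−0.31).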

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

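The tests of RNA degradation, of ribosomal RNA, of the signal level list by list, of the red pulp genes outside the macrophage list and of B lineage genes array by array were chosen after the result was seen, and the other tests of the closing section's explanations were written before theirs. Among 19 mouse control probe sets, which enter no gene comparison, 4 were higher on both REL arrays than on every WT array, where chance gives 10% in each direction. Several of the 19 measure parts of the same transcript, so they are not independent and the count cannot be weighed against that share. The 18S ribosomal RNA probe sets stood at REL over WT ratios of 1.45 (3′ part), 3.25 (5′ part) and 1.38 (middle part), and the middle pyruvate carboxylase probe set at 1.64. These are ratios of mean signals.

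The first pattern weighed is the rise of macrophage markers, for which a candidate explanation is a small number of macrophages that passed the eGFP gate, although the sort for germinal centre B cells should remove them, and loss of Rel as a cause was not tested separately from the sort, since REL cells alone were sorted as eGFP-positive. Genes of red pulp macrophages, the iron-recycling macrophages of spleen, had a median of 2.40 over 11, but 6 of these are in the macrophage list itself. The other 5, with Mrc1, Spic and Cd5l among them, had a median of 2.17 (bootstrap 95% interval over genes 0.33 to 3.04). Mrc1 and Spic had WT signals of 3.78 to 17.6 and 1.18 to 15.1, below the filter level (23.1), and passed it through their REL signals. Red pulp genes dim in WT that did not rise would be left out, so this median is no independent check. Without REL replicate 1 Cd5l was at 1.21 and Spic at 0.92 (from another probe set, 2.66 from the same). Neutrophil and monocyte genes had a median of −0.56 over 4 (interval −1.65 to 0.58), and although it met the bound set beforehand against myeloid cells of every kind, that bound was wrong for fewer than 5 genes that went both ways with Camp and F13a1 near the floor, so such cells stay open. Abundant macrophage transcripts had a median of 0.10 over 21 genes, at percentile 95.01 of matched random lists. Their median deviation from the WT mean was −0.10 and 0.02 on REL replicates 1 and 2 and −0.08 to 0.08 on the WT arrays. Neither REL array lay above every WT array. Lyz2 (3.08) and Maf (2.62; 0.07 without REL replicate 1 from another probe set, 1.53 from the same) were higher. Ctsb (−0.06), Cst3 (−0.25) and Fth1 (−0.15), whose high WT signals would hide a small share, were not (under median centring Ctsb was at 0.11 and Fth1 at 0.02). Fcer1g (0.36), Tyrobp (0.31), Cd68 (0.37), Lipa (0.23) and Ms4a7 (−0.97), with WT signals of 66.3 to 486, were not at an unadjusted p under 0.05 either, but Fcer1g and Tyrobp turned without REL replicate 1 (both −0.24) and Cd68 and Lipa without REL replicate 2 (−0.49 and −0.16), and the signal that a share of macrophages would give on each probe set is not known, so carry-over and expression in the B cells cannot be told apart.

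The second pattern is the fall of the 7 metabolic and protein synthesis lists. B lineage genes lay 0.28 above their members (bootstrap 95% interval 0.18 to 0.36; 0.28 and 0.25 on the REL arrays, −0.06 to 0.04 on the WT arrays). That gap is partly built in, since these lists were chosen because they were called lower, and the interval treats genes as independent. B lineage genes, not chosen in this way, did not fall (median 0.09; −0.00 and 0.17 on the REL arrays, −0.11 to 0.07 on the WT arrays). This argues against fewer B cells as the cause. The B lineage list holds genes of B cells in general, so it cannot show whether the kinds of B cells sorted differed, which stays open. Naive and follicular markers had median deviations of 0.21 and 0.03 on REL replicates 1 and 2 and −0.03 to 0.08 on the WT arrays. Germinal centre markers were at −0.18 and 0.03 in REL and −0.11 to 0.10 in WT, and neither list was called. A shift of all genes at the signal level of the 7 lists stays open. Ribosomal proteins lay at percentile 11.9 of random lists matched on mean level, and at −0.01 with quantile normalization. The other 6 lay at percentile 0.98 or lower and stayed called with quantile normalization (medians −0.33 to −0.12). They were chosen because they were called lower, however, and the random lists treat genes as independent. With an estimated correlation camera called none of them (adjusted p 0.705 to 0.72). RNA quality and composition stay open too, since the higher REL Actb 3′ over 5′ ratio of 1.735 lay within the WT range but 18S ribosomal RNA was higher on both REL arrays than on every WT array. In 3 of the 4 pairs of arrays within a group the array with more 18S (middle part) had the lower median over the lists' members. Those 3 are the pairs of the same 3 WT arrays. The REL pair went the other way, with more 18S on replicate 2 (13417 against 11953) and the higher median there (−0.08 against −0.28). The calls, as given above, were lost without REL replicate 1. Relative to the median of all genes (then −0.10) glycolysis was at −0.13 and the aminoacyl-tRNA synthetases at −0.16, against −0.21 and −0.24 with it. The TCA cycle was then at −0.05, MYC targets at −0.02, oxidative phosphorylation and the proteasome at 0.01 and ribosomal proteins at 0.11. Without REL replicate 2 oxidative phosphorylation was at −0.29 and the proteasome at −0.31. Median deviations of the synthetases were −0.25 and −0.26 on REL replicates 1 and 2 (lowest WT array −0.07). Those of glycolysis were −0.31 and −0.22 (lowest WT array −0.17), so the fall of these lists was not on REL replicate 1 alone. For the other lower lists a difference of REL replicate 1 alone stays open as the cause. Of the 10 splits of the 5 arrays into 3 and 2, 4 called at least 7 lists in 1 direction, the real one included, with a highest of 10 where REL replicate 1 was set apart with WT replicate 1, which points to a structure of the arrays, 10 splits are too few for a share under 0.05, and an effect of Rel loss stays open and untested beyond the group comparison.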

How the results depend on the processing

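The alternatives that keep the probe sets of the full comparison while leaving out a REL array or adding a pseudocount of 1, and the random lists, were chosen after seeing the data. Those probe sets had been picked with the left-out REL array included, so such fits do not fully leave it out. Rel stayed below WT in every alternative run and was never called (adjusted p 0.237 to 0.769). The other 123 named genes kept their direction in all but 46 of 2070 values, 102 of them throughout. The 20 lists not called reversed in 48 of 377 values and 7 never did. The macrophage list stayed called in 17 of 19 alternatives, with a median of 0.65 with no filter. Oxidative phosphorylation, the TCA cycle, MYC targets and the proteasome did in 13 of 19, glycolysis and the aminoacyl-tRNA synthetases in 11, ribosomal proteins in 10, and the stromal list in 7 of 18, since the 60% filter left it too few members. Leaving out a REL array leaves 1 sample, assumed to vary like WT. Where no cause is named, the cause was not tested. Dim probe sets near the filter vary most, and MAS5 signal over background limits them.

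The replicate block (replicate number as a block) called 10 genes higher and 8 lower, with 1 residual degree of freedom. The block turned the apoptosis (−0.07), dark zone (0.03), plasma cell (−0.02) and unfolded protein response (−0.13) lists, and it changed the call of none of the 9 lists called. WT replicate 3 shares its number with no REL array, so it did not enter the block's group difference. Glycolysis had a median of −0.20 both with the block and without WT replicate 3, and was not called in the latter (camera adjusted p = 0.0566). The block's prior degrees of freedom were 22.9 in place of 6.8. Deviations of same-numbered arrays correlated at −0.04 and −0.02, so the numbers were not shown to pair the arrays.

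Genes called higher were 0 with a pseudocount of 1 or 64, a pseudocount of 1 on the full probe sets (where Vcam1 was at 7.58, adjusted p = 0.0504), no filter, the 60% filter, the mean of probe sets, no trend and all probe sets, and 3 with median centring. Genes called lower were 1 with quantile normalization, Mrpl33 (−1.49, limma adjusted p = 0.0246, against 0.0518 in the main comparison). The Mrpl33 difference ran from −1.59 to −1.42 when 1 array was left out in turn. Leaving out 1 array gave 0 to 3 higher and 0 to 5 lower, and with the full probe sets 3 higher and 5 lower without REL replicate 1 and 1 lower without REL replicate 2.

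Lists called lower were 0 with median centring, no trend, an estimated correlation, fry, and the full probe sets without REL replicate 1, and 0 to 9 when 1 array was left out (5 without WT replicate 2, 4 without WT replicate 3). Lists called higher were 1 with a pseudocount of 1, no filter, the 60% filter, median centring, the mean of probe sets, no trend, fry and the full probe sets without REL replicate 1, 0 with an estimated correlation, and 0 to 2 when 1 array was left out. With median centring and without the trend the called lists were as far from the median log2 change of all genes as before (oxidative phosphorylation −0.15). The list test compares t statistics, which weigh each change by its standard error. The log2 distance therefore does not show why these calls ended. Against level-matched random lists 7 were lower, the 6 called other than ribosomal proteins (percentile 11.9) with DNA replication and G1/S (1.67), and 3 higher, the macrophage, the stromal (99) and the natural killer and dendritic cell (99.5) lists.

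Directions of genes turned as follows. With median centring Ikbkb was at 0.10, Ikbkg at 0.03, Ctsb at 0.11, Fth1 at 0.02 and Ms4a1 at 0.06, and with the mean of probe sets Ikbkb was at 0.06, Rps6 at 0.56, Sdha at 0.16 and Ctsb at 0.17. With a pseudocount of 1 Rsad2 was at 0.45, from another probe set. With the full probe sets, without REL replicate 1 Ikbkb was at 0.07, Ikbkg at 0.85, Nfkbia at 0.00, Ctsb at 0.01, Ebf1 at −0.08 and Fcer1g and Tyrobp at −0.24, and without REL replicate 2 Bcl3 was at 0.06, Nfkb2 at 0.29, Relb at −0.19, S100a9 at 0.23, Cd79a at −0.02, Cd68 at −0.49 and Lipa at −0.16. Leaving out 1 array in turn gave ranges of −0.70 to 0.06 for Bcl3, −0.21 to 0.07 for Ikbkb, −0.65 to 0.85 for Ikbkg, −1.07 to 0.29 for Nfkb2, −0.01 to 0.14 for Nfkbia, −0.03 to 0.24 for Nfkbib, −0.19 to 0.46 for Relb, −3.29 to 0.96 for Rsad2, −2.31 to 1.26 for Sdc1 (for both the highest from another probe set), −3.53 to 0.23 for S100a9, −0.12 to 0.01 for Ctsb, −0.02 to 0.17 for Cd79a, −0.08 to 0.11 for Ebf1, −0.24 to 0.95 for Fcer1g, −0.24 to 0.86 for Tyrobp, −0.49 to 1.23 for Cd68 and −0.16 to 0.62 for Lipa.

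The list test turned direction, with these medians, as follows. By fry, which does not compare with other genes, apoptosis was at 0.00, dark zone at −0.05, germinal centre markers at −0.03 and MHC class II at −0.05. Apoptosis was at −0.06 with the 60% filter and 0.01 with quantile normalization, T cell markers at −0.05 with no filter, and interferon genes at 0.11 with the mean of probe sets and 0.19 with a pseudocount of 1. With the full probe sets and without REL replicate 1, ribosomal proteins were at 0.01, G2/M at 0.02, sterol synthesis at −0.02 and T cell markers at −0.21. Without REL replicate 2 apoptosis was at −0.17, dark zone at −0.13, erythroid markers at −0.25, germinal centre markers at −0.18, interferon genes at 0.17, light zone at −0.13, MHC class II at −0.19, NF-kB targets at −0.17 and plasma cell genes at −0.01.

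Leaving out 1 array in turn gave these ranges of medians for the lists that turned: apoptosis −0.17 to 0.01, ribosomal proteins −0.26 to 0.01, dark zone −0.13 to 0.06, erythroid −1.07 to 0.24, stromal −0.11 to 0.55, G2/M −0.23 to 0.02, germinal centre markers −0.19 to 0.03, interferon −0.23 to 0.29, light zone −0.13 to 0.12, MHC class II −0.20 to 0.14, NF-kB targets −0.17 to 0.20, plasma cell −0.02 to 0.21, sterol −0.19 to −0.02, T cell −0.45 to 0.30 and unfolded protein response −0.13 to 0.14.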

Other observations

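The tests in this part were written before their results were seen, except the comparison of B lineage genes with random lists. A list of 18 B lineage genes, some of them also in the germinal centre and naive B cell lists and not itself tested with camera, had a median of 0.09 (bootstrap 95% interval 0.01 to 0.18), with 14 higher. It lay at percentile 99.88 of random lists matched on mean level, which treat genes as independent. Among its members were Cd79a at 0.07, Cd22 at 0.18, Ms4a1 at −0.11 (0.06 under median centring), Ebf1 at 0.02 and Cd180 at 0.29, and no member was at an unadjusted p under 0.05 in limma.

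For single genes, the real grouping called 1 gene and each of the other 9 splits of the 5 arrays called 0. In all 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05.

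A floxed allele can carry sequence of another strain around the target, so it was asked whether genes next to Rel held more differences than others. Of the 40 measured genes next to Rel, as many on each side, 3 (Xpo1, Lgalsl and Clhc1) were at an unadjusted p under 0.05, or 7.5%, against 8.23% of the other 12041 genes (one-sided Fisher's exact p = 0.65). All 3 were lower, with ranges of −0.58 to −0.22, −3.11 to −1.68 and −2.16 to −1.91 when 1 array was left out in turn. No excess was found in this count, and with 40 genes a small excess could be missed.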
